A study of Rattus norvegicus with 18 samples.

How the data were processed

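Gene expression was measured in 2 established rat thyroid cell lines with 1-colour Affymetrix arrays. FRTL5 is a differentiated thyrocyte line. FRT/TSHR is a de-differentiated thyroid line that, as its name states, carries the receptor for thyroid-stimulating hormone (TSH). Each line was sampled without hormone (basal) and after 30 min and 17 h of bovine TSH. Each of the 6 groups had 3 biological replicates, which gave 18 arrays. Per the labels' protocols, FRTL5 cells were kept for 5 days in TSH-free 5H medium and received TSH at 0.1 U/L, while FRT/TSHR cells had a modified F12 medium (Coon's) and received 1 U/L. Cells of both lines spent 12 h without serum before stimulation. Total RNA (10 µg) was turned into biotin-labelled cRNA, per the labels.

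The deposited table held log2 expression values per probe set. Per the submitters' processing notes the authors made them with RMA, which corrects background, normalizes across arrays and summarizes the probes of a probe set. The RMA version and its settings were not given in the sources used here. The log2 scale was read from the values, which lay between 2.61 and 13.58 with array medians of 5.47 to 5.59. The scanner files were not analysed here, so the background correction and the summary step were not varied, and detection above background was not measured. Of 8799 probe sets in the table, 59 control probe sets were left out and 8740 were tested, with no filter on low signal.

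Gene names came from the platform annotation. It gave 1 gene symbol to 7006 probe sets, several to 308 and none to 1426, and probe sets with several symbols named no gene. Of the 7006, 6985 were matched by gene number to the GRCr8 reference table, and 0 symbols changed. No genome build is named for the probe sets, so no coordinates are given. For the named genes and the gene lists each of 4736 genes was represented by its probe set with the highest mean. Of these genes, 1561 had several probe sets, and disagreements are stated where they change a result.

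Differences were tested with limma 3.58.1 in R 4.3.3. A model of 6 group means was fitted to all 18 arrays with lmFit and eBayes, with 12 residual and 3.597 prior degrees of freedom. Tests were two-sided, and p-values were adjusted with the Benjamini-Hochberg method over the 8740 probe sets within each of 9 comparisons. A probe set passed at an adjusted p under 0.05. The comparisons were each TSH time against basal within a line, 17 h against 30 min within a line, the basal lines against each other, and the difference of the TSH effect between lines (FRT/TSHR effect minus FRTL5 effect) at each time. Cell line, TSH dose and medium differed together, so the comparisons between lines cannot tell them apart. Both TSH times of a line were compared with the same basal group, and the labels name no untreated group for either time. Changes with time or handling therefore cannot be told apart from effects of TSH. Errors of log2 differences are limma standard errors (SE), and group values are mean ± SD of 3 arrays. The number of arrays limits the precision.

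The design, the tests, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 10 largest positive and the 10 largest negative differences that passed and whose groups did not overlap (without the overlap condition for differences between effects, and 5 at each end for 17 h against 30 min). It also took up to 4 members of each list with the smallest p, and Tshr, Tg, Slc5a5, Pax8, Nkx2-1, Foxe1, Fos, Egr1, Nr4a1, Crem and Per1 where measured. No probe set was named Per1 here. Of the genes named in advance 1 more is not reported here, and the text does not print all genes that the other parts of the rule took. The 24 lists covered thyroid differentiation, immediate early genes, cAMP-CREB targets, cAMP pathway components, MAP kinase feedback, DNA replication (S phase), mitosis (G2/M), G1 cyclins and CDK inhibitors, ribosome biogenesis, cholesterol synthesis, ER protein folding, glycolysis and glucose uptake, epithelial junctions and keratins, mesenchymal markers, C cell and neuroendocrine markers, endothelial markers, leukocyte markers, MHC class I and interferon response, TGF-beta and matrix response, growth factors and their receptors, clock genes, heat shock, antioxidant enzymes, and lysosomal proteases and endocytosis. Some genes stood on more than 1 list, and 14 of the 23 measured cAMP-CREB targets were also on another list. Lists were tested with camera in limma, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. Its p-values were adjusted together over 168 tests (24 lists in 7 comparisons). Of the 33 list calls, 6 also passed with the correlation estimated per list, and 1 (immediate early genes in FRTL5 at 30 min) when the replicate block was added to that. The adjusted p is given where the call was lost.

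The labels number the replicates of every group from 1 to 3. Within each line, deviations from the group means were correlated between arrays of the same number in all 6 pairs of groups (lowest r 0.148 and highest 0.798), so the numbers were taken to pair the arrays. In FRT/TSHR arrays of different numbers correlated at -0.0296 or lower. In FRTL5 they correlated at up to 0.391 (30 min with basal), 0.420 (17 h with basal) and 0.628 (17 h with 30 min). There the values do not settle how the arrays numbered 2 and 3 pair. Between the basal groups of the lines the correlations ran from -0.00252 to 0.351, and those arrays were not taken as paired. The main fit did not use the pairing. The blocked fit, with the replicate number as an added term shared by both lines and 10 residual degrees of freedom, was an alternative. It therefore also matched arrays between the lines, which were not taken as paired. Only the separate block in each line follows the pairing as taken here. The other alternatives were re-centring each array, quantile normalization, a filter at the 25th percentile of signal, array weights, an intensity trend in the prior, a fit of only the arrays compared, each array left out in turn, a stricter threshold and a 2-fold minimum. For the lists they were a correlation estimated per list, the fry test, the mean of all probe sets of a gene and the blocked fit. The pseudocount alternative was not run because the table already was on a log2 scale. A separate block in each line, a crossed pairing and fits without the arrays numbered 1 were added after seeing the data.

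The fit was tested on simulated data with 200 of 8740 probe sets changed by a known amount, in 5 draws. For FRT/TSHR at 30 min it recovered 25% of changes of 0.5 (log2), 84.6% of changes of 1 and 98.4% of changes of 2. For FRT/TSHR at 17 h these shares were 31.8%, 83% and 98.2%, and for FRTL5 at 17 h 29.7%, 83.2% and 98.3%. For the difference of the 17 h effects it recovered 0.3%, 63% and 94.3%. A shift of 0.5 of the 17 cholesterol synthesis genes, simulated for FRTL5 at 17 h, was called in 20 of 20 draws, while 2 of 460 tests of the other lists were called. The simulated genes varied independently of each other, and no replicate effect was added. These counts therefore do not show how often lists of correlated genes are called without a change. The Benjamini-Hochberg adjustment is stricter when fewer probe sets change. With fewer than 200 changed, the shares recovered may be lower than those given here.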

Results

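The series followed the response of differentiated FRTL5 and de-differentiated FRT/TSHR rat thyroid cells to TSH over time. Expression was measured in 3 biological replicates of each line at basal, 30 min and 17 h. Line was the main difference between arrays, since the first principal component held 69.8% of the variance and separated the lines. The second held 9.01% and separated the arrays numbered 1 of both lines from all other arrays. The third held 4.96% and set the FRTL5 17 h arrays apart. The median SD of a probe set between replicates was 0.162 in FRTL5 and 0.149 in FRT/TSHR groups (log2). At most 0.0229% of the values were identical between any 2 arrays, and the closest pair correlated at r = 0.996. In FRTL5 the arrays numbered 1 of all 3 groups differed from the rest in signal along the beta-actin transcript. Their 3' minus 5' difference was 1.13 to 1.22 (log2), against at most 0.28 on the other 15 arrays. This did not follow TSH, but counts without these arrays are given where they moved by over 1.5 times, along with the number of named calls lost.

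The first comparison asked what TSH changed in FRTL5 cells within 30 min. Immediate early genes rose. Egr1, a zinc finger transcription factor induced by growth signals, rose 15.1-fold, from 6.86 ± 0.86 to 10.78 ± 0.73 (log2, mean ± SD, n = 3; log2 difference 3.91 ± 0.58, adjusted p = 0.0044). The orphan nuclear receptors Nr4a1 and Nr4a3 rose by 3.41 ± 0.33 (adjusted p = 8.9e-05) and 1.46 ± 0.10 (adjusted p = 9.9e-07). Fos, a subunit of the AP-1 transcription factor, rose by 2.45 ± 0.46 (adjusted p = 0.035), and its 30 min arrays had an SD of 1.52. Dusp1, a phosphatase that inactivates MAP kinases, rose by 2.08 ± 0.25 (adjusted p = 0.00059). The matricellular gene Ccn1 rose by 2.58 ± 0.45 and the transcription factor gene Myc by 1.39 ± 0.24 (adjusted p = 0.017 for each). Id1, an inhibitor of helix-loop-helix factors, rose by 1.07 ± 0.15 (adjusted p = 0.0028).

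As a list, the immediate early genes rose (camera adjusted p = 3.3e-30, and 0.0168 with an estimated correlation). Of 35 measured members 7 rose, or 16 when adjusted over the list alone, 28 had a higher value, and the median difference was 0.55. The cAMP-CREB targets rose as a list as well (adjusted p = 3.8e-08, and 0.0333 with an estimated correlation, but 0.103 with the block added), with 4 of 23 members called, 5 when adjusted over the list alone, and a median of 0.10. The members that moved most, Nr4a1, Fos, Dusp1 and Nr4a3, also stood on other lists. The MAP kinase feedback list rose (adjusted p = 0.00015, and 0.0333 with an estimated correlation, but 0.103 with the block added) with 1 of 9 members called, or 3 when adjusted over the list alone. Of these 9, Dusp5 and Dusp6 had differences of 1.45 ± 0.33 and 0.94 ± 0.29 that did not pass. None of the other 21 lists passed at 30 min. The thyroid differentiation list had a median of -0.05 (adjusted p = 0.662), and Slc5a5, Tg, Pax8 and Tshr had differences of -0.09, -0.20, -0.02 and -0.08. The cholesterol synthesis and DNA replication lists had medians of 0.08 and -0.08 (adjusted p = 0.610 and 0.195).

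In limma with Benjamini-Hochberg adjustment 21 probe sets of 12 genes passed at 30 min in FRTL5, all upward, and 241 (2.76%) had an unadjusted p under 0.05. Another probe set than the representative one carried the call for Junb (1.95 ± 0.29), Zfp36 (1.56 ± 0.29), Nr4a2 (1.21 ± 0.18) and Klf10 (0.81 ± 0.15), which are named here after their values were seen. The count was 44 without FRTL5 30 min replicate 1, 12 without FRTL5 30 min replicate 2 and 13 without FRTL5 basal replicate 2, and 45 without all FRTL5 arrays numbered 1. The calls of Fos, Ccn1 and Myc were each lost in 5 of 6 fits that left out 1 array, with adjusted p up to 0.304 (Fos, without FRTL5 30 min replicate 2) and 0.163 (Ccn1 and Myc, without FRTL5 30 min replicate 3). A fit of only the 6 arrays compared called 2 probe sets and lost 7 of the 8 named calls, all but Nr4a3, with adjusted p of 0.103 for Egr1, Nr4a1, Dusp1 and Id1, 0.254 for Myc, 0.433 for Ccn1 and 0.999 for Fos. Groups did not overlap for 6.35% of all probe sets, against 10% by chance if the arrays were unpaired. Arrays of the same number were taken as paired within a line, so 10% is not the share without change here.

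At 17 h the iodide transporter gene Slc5a5 and genes of cholesterol synthesis and DNA replication rose in FRTL5, the DNA replication list not with an estimated correlation (adjusted p = 0.135). Slc5a5, the sodium iodide symporter of thyroid cells, showed the largest rise among the named genes. It went from 6.96 ± 0.21 to 9.58 ± 0.40 (log2, mean ± SD, n = 3), a 6.14-fold rise (log2 difference 2.62 ± 0.18, adjusted p = 1.9e-06). The potassium channel gene Kcnj15, also on the thyroid list, rose by 1.61 ± 0.16 (adjusted p = 8.2e-05). The sterol genes Cyp51, Acat2 and Fdps rose by 2.30 ± 0.26, 2.26 ± 0.29 and 1.99 ± 0.19 (adjusted p = 0.00027, 0.00049 and 7.5e-05). Pcna, the sliding clamp of DNA polymerases, rose by 1.71 ± 0.41 (adjusted p = 0.027), and Cdk1, the kinase that drives entry into mitosis, rose by 1.26 ± 0.26 (adjusted p = 0.012). The Pcna call was lost in 5 of 6 fits without 1 array, with adjusted p up to 0.121 without FRTL5 basal replicate 3, and the Cdk1 call without FRTL5 basal replicate 2 (adjusted p = 0.0536).

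**Figure D1:**
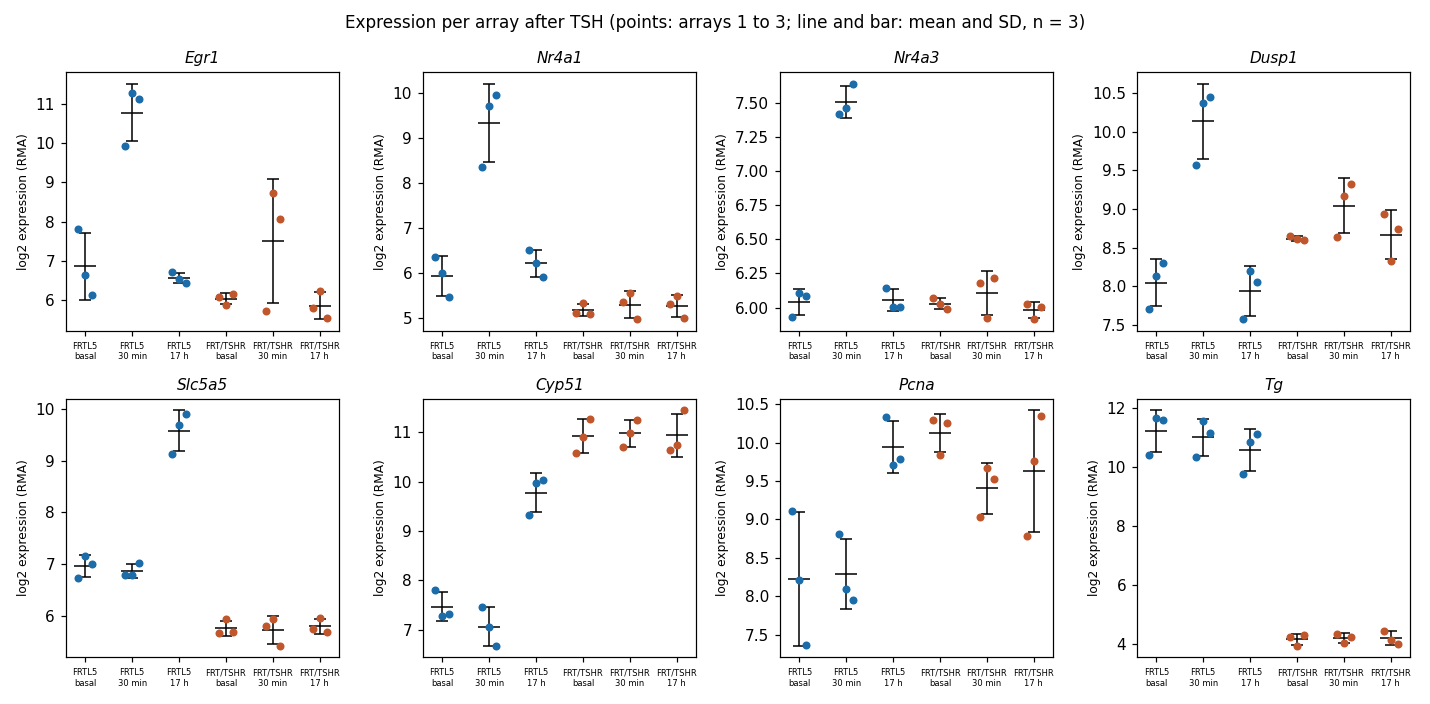
Expression of 8 genes in each array (log2 RMA value), by cell line and time of TSH; points are arrays and lines with bars are mean and SD of 3 arrays. Egr1, Nr4a1, Nr4a3 and Dusp1 were high in FRTL5 at 30 min, Slc5a5, Cyp51 and Pcna at 17 h, and Tg was lower in every FRT/TSHR array than in any FRTL5 array.

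All 17 measured cholesterol synthesis genes had higher values at 17 h, with a median difference of 0.82. Of these 9 rose, or 14 when adjusted over the list alone, and the list passed (adjusted p = 4.3e-20, and 0.0333 with an estimated correlation, but 0.103 with the block added). Idi1 rose by 1.54 ± 0.28 and Hsd17b7 by 1.23 ± 0.17. All 17 DNA replication genes were higher as well (median 0.74), 8 rose, or 14 when adjusted over the list alone, and the list rose (adjusted p = 8.65e-15, but adjusted p = 0.135 with an estimated correlation). Next to Pcna these included the primase genes Prim1 (1.07 ± 0.19) and Prim2 (0.71 ± 0.14), the polymerase gene Pola1 (0.81 ± 0.18), the helicase gene Mcm5 (1.56 ± 0.38) and Tyms (0.94 ± 0.14), which makes thymidylate. The mitosis list rose (adjusted p = 0.0054, but adjusted p = 0.469 with an estimated correlation), with 15 of 16 members higher and Cdk1 and Top2a (1.08 ± 0.23) called, or 4 members when adjusted over the list alone. With 1 array left out the calls of Pola1, Top2a and Prim2 were lost in 4, 3 and 1 of 6 fits (adjusted p up to 0.0930, 0.0603 and 0.0504, each without FRTL5 17 h replicate 2). The ER protein folding list rose too (adjusted p = 0.0032, but adjusted p = 0.343 with an estimated correlation), with 1 of 16 members called, also over the list alone, Pdia6 (0.53 ± 0.12), a call lost in 4 of 6 such fits (adjusted p up to 0.109, without FRTL5 17 h replicate 2).

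Other genes fell. The clock list fell (adjusted p = 0.0084, but adjusted p = 0.125 with an estimated correlation), with 2 of 9 members called, or 3 when adjusted over the list alone. These were Dbp, an output gene of the circadian clock (-0.96 ± 0.12, adjusted p = 0.00045), and the repressor gene Per2 (-0.68 ± 0.15, adjusted p = 0.019). The lysosomal list fell (adjusted p = 0.0098, but adjusted p = 0.0757 with an estimated correlation), with 4 of 18 members called, or 5 when adjusted over the list alone. The cathepsins Ctsb and Ctsh fell by 0.73 and 0.56 on the log2 scale, Ppt1 by 0.77 and Lamp1 by 0.50. With 1 array left out Ctsb, Ctsh and Lamp1 each lost their call in 5 of 6 fits, with adjusted p up to 0.122 (without FRTL5 17 h replicate 2), 0.187 and 0.134 (without FRTL5 basal replicate 2). Ppt1 lost it in 1 (0.0603, without FRTL5 17 h replicate 2), and Per2 and B2m in 4 each (up to 0.0785 and 0.101, without FRTL5 17 h replicate 2). This list no longer passed without FRTL5 basal replicate 2 (adjusted p = 0.072) or FRTL5 17 h replicate 1 (adjusted p = 0.0516). Among the MHC class I and interferon genes B2m (-0.99 ± 0.23), Irf7 (-0.68 ± 0.12) and RT1-CE16 (-0.63 ± 0.11) fell, or 5 members when adjusted over the list alone, while the list of 20 genes did not pass (adjusted p = 0.199). The largest falls under the naming rule were those of Selenow (-1.43 ± 0.29), Ech1 (-1.38 ± 0.19), Tcp11l2 (-1.37 ± 0.28) and Xdh (-1.34 ± 0.26), of which Ech1 kept its call in all 6 fits. The calls of the other 3 were lost in 2, 1 and 1 fits, with adjusted p up to 0.0620 (without FRTL5 basal replicate 2), 0.0571 (without FRTL5 17 h replicate 3) and 0.0504 (without FRTL5 17 h replicate 2). The antiproliferative gene Btg1 fell by 1.10 and the tetraspanin gene Cd9 by 1.15 on the log2 scale.

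The thyroid differentiation list as a whole did not pass at 17 h (adjusted p = 0.448, median -0.02). Slc5a5 and Kcnj15 were its only members called of 14, and over the list alone 2 rose and 1 fell. Without FRTL5 17 h replicate 1 the list passed (adjusted p = 0.0276). Tg, which encodes thyroglobulin, had a difference of -0.64 ± 0.37 (adjusted p = 0.555), and none of its other 3 probe sets passed. The transcription factor gene Pax8 had a difference of -0.80 ± 0.23 (adjusted p = 0.072), which passed in the blocked fit (adjusted p = 0.039). The representative probe sets of Tshr, Nkx2-1 and Crem did not pass (0.16, -0.05 and 0.40), while another probe set of each did, with -0.59, -0.61 and 0.45 (adjusted p = 0.0248, 0.0236 and 0.0234). Foxe1, Fos, Egr1 and Nr4a1 had differences of -0.04, 0.04, -0.30 and 0.28 that did not pass.

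The remaining lists did not pass in FRTL5 at 17 h. All 9 ribosome biogenesis genes had higher values (adjusted p = 0.115), and this list passed in the blocked fit (adjusted p = 0.0464) and without FRTL5 17 h replicate 2 (adjusted p = 0.0395). The immediate early list had 2 members down, Btg1 and Id1 (-0.68 ± 0.15), and an adjusted p of 0.109, or 0.0497 without FRTL5 17 h replicate 3. Called members of other lists were Hspe1 (0.63, heat shock, list adjusted p = 0.170), Gpx2 (1.15) and Gclm (0.61) upward and Gsta4 (-0.75) downward (antioxidant enzymes, 0.236), Slc16a1 (0.79) and Pgam1 (0.40) upward (glycolysis, 0.316), Spint2 (-0.57, epithelial, 0.188), Ret (-0.36, C cell, 0.800) and Bmp4 (-0.88, TGF-beta and matrix, 0.962). With 1 array left out Hspe1, Slc16a1, Bmp4 and Id1 lost their calls in 5, 5, 5 and 3 of 6 fits, with adjusted p up to 0.157, 0.0845, 0.187 and 0.0709 (without FRTL5 17 h replicate 1, FRTL5 basal replicate 2, FRTL5 basal replicate 2 and FRTL5 17 h replicate 3). No member was called of the cAMP-CREB targets (0.305), cAMP pathway components (0.608), MAP kinase feedback (0.654), G1 cyclins (0.482), mesenchymal (0.673), endothelial (0.635), leukocyte (0.873) or growth factor (0.809) lists. Adjusted over each list alone, 2 heat shock and 4 glycolysis genes rose, 3 antioxidant genes rose and 2 fell, and 3 epithelial, 1 C cell and 1 TGF-beta gene fell. The heat shock list passed without FRTL5 basal replicate 1 (adjusted p = 0.0236) and the antioxidant list without FRTL5 17 h replicate 1 (adjusted p = 0.0276).

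In limma 311 probe sets passed in FRTL5 at 17 h, of which 143 rose and 168 fell, in 99 and 132 genes. At least 2-fold changes were called for 91 of them, 60 up and 31 down. The blocked fit called 508 and held all 311. The count was 152 without FRTL5 17 h replicate 2, 159 without FRTL5 17 h replicate 3 and 190 without FRTL5 basal replicate 2. Of the 48 named genes called here, 25 lost their call in at least 1 fit without an array, 22 in a fit of only the 6 arrays compared and 18 without the FRTL5 arrays numbered 1. Mcm5, Pgam1 and Ret lost it in all 6, with adjusted p up to 0.117 (without FRTL5 17 h replicate 1), 0.133 (without FRTL5 basal replicate 2) and 0.210 (without FRTL5 17 h replicate 2). Groups did not overlap for 15.4% of probe sets, against 10% by chance if the arrays were unpaired, which they were not taken to be.

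Within FRTL5 the early rise had ended by 17 h. Egr1, Nr4a1, Ccn1, Jun and Fos fell between 30 min and 17 h, with differences of -4.21, -3.13, -2.94, -2.42 and -2.41. Slc5a5, Cyp51, Acat2, Mcm6 and Fdps rose over the same interval, by 2.71 ± 0.18, 2.71 ± 0.26, 2.28 ± 0.29, 2.00 ± 0.52 and 1.83 ± 0.19. Of the 21 probe sets that rose at 30 min, all 21 were lower at 17 h than at 30 min, 0 were still called up against basal, and 1, of Id1, was called down. Their median difference from basal went from 2.08 to -0.05. In limma 368 probe sets differed between 17 h and 30 min, 163 up and 205 down, and the blocked fit called 584. Pax8 had a difference of -0.77 (adjusted p = 0.073), which passed in the blocked fit (adjusted p = 0.041). The count was 145, 219, 230 and 200 without 30 min replicate 2, 30 min replicate 3, 17 h replicate 2 and 17 h replicate 3, and Mcm6 lost its call in all 6 fits without an array (adjusted p up to 0.122). Without 30 min replicate 2 the fall of Fos had an adjusted p of 0.0503.

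In FRT/TSHR cells no gene passed at either time of TSH. At 30 min Egr1 had the largest difference among the named genes, 1.47 ± 0.58 (adjusted p = 1.00), with 7.51 ± 1.58 against 6.04 ± 0.15 at basal (n = 3). Its arrays read 5.72, 8.74 and 8.06. Fos, Nr4a1 and Dusp1 had differences of 0.34 ± 0.46, 0.12 ± 0.33 and 0.43 ± 0.25. At 17 h Slc5a5 was at 5.79 ± 0.14 against 5.76 ± 0.14 at basal, a difference of 0.03 ± 0.18. Tg, Tshr, Pax8, Nkx2-1 and Foxe1 had differences of 0.04, 0.12, 0.08, -0.09 and 0.07 at 17 h.

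Several lists moved in FRT/TSHR although no member was called, neither over all probe sets nor over any list alone. At 30 min the cAMP-CREB targets were higher (21 of 23 genes, median 0.13, adjusted p = 0.00056, but adjusted p = 0.134 with an estimated correlation). All 9 clock genes were higher (adjusted p = 0.0409, but 0.229 as an adjusted p with an estimated correlation). Lower were all 17 DNA replication genes (median -0.30, adjusted p = 2.4e-06, but adjusted p = 0.436 with an estimated correlation) and all 16 mitosis genes (median -0.34, adjusted p = 4.5e-09, but adjusted p = 0.076 with an estimated correlation). The MHC class I list (14 of 20 lower) and the antioxidant list (18 of 26 lower) had adjusted p = 0.0218 and 0.0409, but adjusted p = 0.229 and 0.569 with an estimated correlation. The immediate early list had 27 of 35 genes higher and did not pass (median 0.17, adjusted p = 0.160), but passed without FRT/TSHR 30 min replicate 1 (adjusted p = 0.0222). The MAP kinase feedback list, with all 9 genes higher, had an adjusted p of 0.0589 and passed in the blocked fit (adjusted p = 0.0439) and without FRT/TSHR 30 min replicate 1 (adjusted p = 0.0221). The ribosome biogenesis list passed without basal replicate 1 (adjusted p = 0.0190) and the G1 cyclin list without 30 min replicate 2 (adjusted p = 0.0323).

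At 17 h in FRT/TSHR the DNA replication list (16 of 17 lower, median -0.35, adjusted p = 1.7e-08) and the mitosis list (14 of 16 lower, median -0.38, adjusted p = 1.1e-09) were again lower, but with adjusted p = 0.355 and 0.0757 with an estimated correlation. The cholesterol synthesis list was lower (15 of 17, median -0.25, adjusted p = 6.5e-05, but adjusted p = 0.355 with an estimated correlation). The ER protein folding list (13 of 16 higher) and the heat shock list (9 of 12 higher) were higher with adjusted p = 0.0086 and 0.00018, but adjusted p = 0.397 and 0.266 with an estimated correlation. The medians of single arrays moved these lists. The DNA replication genes had medians of 7.21, 6.96 and 6.95 in the basal arrays, 6.45, 6.94 and 6.93 at 30 min, and 6.18, 6.86 and 7.29 at 17 h. That list no longer passed without 30 min replicate 1 (adjusted p = 0.238) or without 17 h replicate 1 (adjusted p = 0.634), and the 17 h replicate 1 also carried the cholesterol list (adjusted p = 0.0763 without it). The heat shock list was lost without basal replicate 2 (adjusted p = 0.073). The ER list was lost without basal replicate 1 (adjusted p = 0.242) and turned direction without 17 h replicate 3 (adjusted p = 0.982). The MHC and glycolysis lists passed at 17 h only without 17 h replicate 1 (adjusted p = 0.0282) and 17 h replicate 3 (adjusted p = 0.0219), among the single arrays left out. At 30 min the MHC call was lost without basal replicate 1, 30 min replicate 2 or 30 min replicate 3 (adjusted p = 0.109, 0.314 and 0.121). The clock call was lost without basal replicates 1 or 2 or 30 min replicates 1 or 3 (adjusted p = 0.104, 0.143, 0.351 and 0.0801), and the antioxidant call without basal replicates 1 or 3 or 30 min replicate 3 (adjusted p = 0.121, 0.236 and 0.613).

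In limma with Benjamini-Hochberg adjustment 0 of 8740 probe sets passed in FRT/TSHR at 30 min and 0 at 17 h, and the blocked fit also called 0 at each time. At an unadjusted p under 0.05 there were 208 and 108 (346 and 190 in the blocked fit). The 208 and 108 were 2.38% and 1.24% of probe sets. Unchanged probe sets would give a share of 0.05, so these counts are no sign of a response. The main fit did not use the pairing, so its p-values may be too large. Between 17 h and 30 min 0 passed, with 179 (2.05%) at an unadjusted p under 0.05, and 8 passed without 30 min replicate 1. Groups did not overlap for 7.84% of probe sets at 30 min and 5.64% at 17 h. The share by chance would be 10% if the arrays were unpaired, which they were not taken to be.

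**Figure D2:**
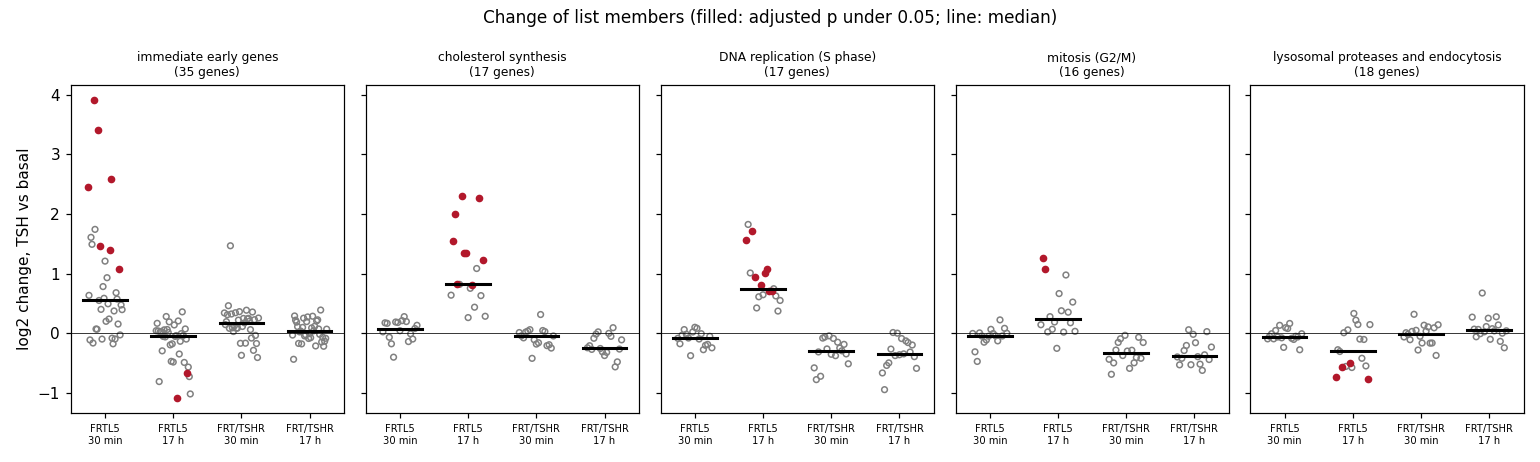
Change after TSH (log2, against basal) of the measured genes of 5 lists in both lines at 30 min and 17 h; each point is a gene, filled where its adjusted p was under 0.05, and the bar is the median. In FRTL5 the immediate early median was 0.55 at 30 min and the cholesterol and DNA replication medians 0.82 and 0.74 at 17 h, while in FRT/TSHR the DNA replication medians were -0.30 and -0.35.

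Without hormone the lines differed widely. The medium differed with the line, so these differences cannot be assigned to the de-differentiated state alone. Thyroglobulin was among the largest differences. Tg was at 4.17 ± 0.19 in FRT/TSHR against 11.21 ± 0.70 in FRTL5 (log2, n = 3; difference -7.04 ± 0.37, adjusted p = 4.7e-10), and its other probe sets were lower in FRT/TSHR as well. Of the thyroid differentiation list 7 of 14 members were lower and 4 higher, or 8 and 4 when adjusted over the list alone, and the list did not pass (adjusted p = 0.239). Lower were also Slc5a5 (-1.20 ± 0.18), Pax8 (-1.21 ± 0.23), Foxe1 (-1.89 ± 0.34) and Kcnj15 (-1.69 ± 0.16). Nkx2-1 had a difference of -1.24 ± 0.50 (adjusted p = 0.086) on its representative probe set and -3.82 (adjusted p = 6.33e-12) on another. Tshr had a difference of 0.04 (adjusted p = 0.912) on its representative probe set, but -0.81, -3.96 and -2.15 on its other 3 (adjusted p = 0.010, 1.06e-07 and 6.42e-09). Which part of the transcript each probe set reads, and which part the introduced receptor holds, is not given in the sources used here, so these values do not measure the introduced receptor.

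Epithelial genes were higher in FRT/TSHR. The cell surface genes Tspan8 (7.89 ± 0.21) and Epcam (6.19 ± 0.11) and the keratin genes Krt8 (5.59 ± 0.18) and Krt18 (4.31 ± 0.20) were higher, as was the tight junction gene Cldn3 (3.72 ± 0.13). Of 12 genes on the epithelial list 9 were higher and 2 lower, both over all probe sets and when adjusted over the list alone. The list passed (adjusted p = 2.3e-06, and 0.0333 with an estimated correlation, but not with the block added to that). The cholesterol synthesis list was higher in FRT/TSHR with 13 of 17 genes called, also when adjusted over the list alone (median 1.75, adjusted p = 5.5e-09, but adjusted p = 0.132 with an estimated correlation), among them Idi1 (3.71), Cyp51 (3.44), Fdps (3.30) and Fdft1 (2.73). DNA replication (10 of 17 higher, median 0.82, adjusted p = 0.00075) and mitosis genes (10 of 16 higher, median 0.77, adjusted p = 0.0027) were higher as well, with 11 and 11 when adjusted over the list alone, but with adjusted p = 0.673 and 0.428 with an estimated correlation. The heat shock list was higher (7 of 12 called, also over the list alone, adjusted p = 0.00046, but adjusted p = 0.308 with an estimated correlation), with Cryab at 3.45 and Hspb1 at 2.22. The lysosomal list was lower, with 9 of 18 genes lower and 1 higher or 9 and 2 when adjusted over the list alone (adjusted p = 0.0060, but adjusted p = 0.0717 with an estimated correlation), among them Ctsc (-2.34), Ctsb (-1.92) and Ppt1 (-1.64).

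Among other named genes S100a4 (6.46), Scd2 (5.75), Anxa1 (5.53), Lgals3 (5.30), Il33 (5.23), Fabp5 (5.02), Capg (4.96), Gstp1 (3.07) and Myc (2.64) were higher in FRT/TSHR. Cpq (-6.33), Sdc2 (-5.95), Ndrg2 (-5.24), Slc25a4 (-4.60), Fgfr1 (-4.50), Cnn1 (-4.49), Timp3 (-4.23), Cd48 (-4.18) and Sod3 (-4.13) were lower. The markers of other cell types did not differ as lists. Of 27 mesenchymal genes 3 were higher and 5 lower (adjusted p = 0.871), of 16 C cell genes 0 and 1 (0.873), of 8 endothelial genes 1 and 0 (0.873) and of 19 leukocyte genes 1 and 1 (0.976). The same counts were obtained when adjusted over each list alone. In limma 2226 probe sets (25.5%) differed between the basal lines, 1161 higher and 1065 lower in FRT/TSHR, in 762 and 720 genes. Of these 999 differed at least 2-fold. Groups did not overlap for 37.0% of probe sets, against 10% by chance.

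The difference of the TSH effects asked whether FRT/TSHR responded less than FRTL5, although at 1 U/L it received more hormone. At 30 min the responses of Nr4a1 (-3.29 ± 0.46, adjusted p = 0.013) and Nr4a3 (-1.38 ± 0.14, adjusted p = 0.0003) were smaller in FRT/TSHR. The Nr4a1 call was lost in 4 of 12 fits without 1 array, with adjusted p up to 0.0666 without FRT/TSHR 30 min replicate 3, and in a fit of only the arrays compared (adjusted p = 0.0823). Egr1 and Fos had differences of -2.45 ± 0.83 and -2.11 ± 0.66 that did not pass. The immediate early list responded less in FRT/TSHR (median -0.41, 27 of 35 lower, adjusted p = 3.1e-14, but adjusted p = 0.0572 with an estimated correlation), and 2 of its genes were called, or 11 lower and 1 higher when adjusted over the list alone. The mitosis list had a median of -0.28 (14 of 16 lower, adjusted p = 0.0031, but adjusted p = 0.430 with an estimated correlation), a call that was lost without FRTL5 basal replicate 1 (0.0611), FRT/TSHR basal replicate 1 (0.214) or FRT/TSHR 30 min replicate 1 (0.118). The cAMP-CREB list (adjusted p = 0.0956) passed without FRTL5 basal replicate 3, FRTL5 30 min replicate 1 or FRT/TSHR basal replicate 1 (0.0136, 0.00429 and 0.0190). The DNA replication list (0.0784) passed without FRT/TSHR basal replicate 2, 30 min replicate 2 or 30 min replicate 3 (0.0402, 0.00656 and 0.00693), and the G1 cyclin list (0.0735) without FRTL5 basal replicate 1, FRTL5 30 min replicate 2, FRT/TSHR basal replicate 1 or FRT/TSHR 30 min replicate 2 (0.0221, 0.0464, 0.0388 and 0.0130). In limma 3 probe sets passed, all negative, with 227 at an unadjusted p under 0.05. The count was 24 without FRTL5 30 min replicate 1, 25 without all FRTL5 arrays numbered 1, and 1 without any of FRTL5 basal replicate 3, FRTL5 30 min replicate 2, FRT/TSHR basal replicate 2 or FRT/TSHR 30 min replicate 3.

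At 17 h the differences were largest for the genes that rose in FRTL5 after TSH. Slc5a5 differed by -2.58 ± 0.26 (adjusted p = 0.0003) and Acat2 by -2.83 ± 0.41 (adjusted p = 0.0040). Cyp51 (-2.28 ± 0.37), Fdps (-2.27 ± 0.27), Hsd17b7 (-1.50 ± 0.24) and Mvd (-1.66 ± 0.37) of cholesterol synthesis passed, as did Prim1 (-1.42 ± 0.27), Tyms (-1.21 ± 0.20), Cdk1 (-1.79 ± 0.36), Top2a (-1.50 ± 0.33) and Dnmt1 (-1.65 ± 0.33). All 17 cholesterol synthesis genes had a lower response in FRT/TSHR (adjusted p = 1.6e-23, and 0.0333 with an estimated correlation, but 0.0798 with the block added), with 5 called or 14 when adjusted over the list alone. All 17 DNA replication genes did too, with 2 called or 16 when adjusted over the list alone (median -1.06, adjusted p = 4.3e-20, but adjusted p = 0.076 with an estimated correlation). The mitosis list had a median of -0.63 (2 called, 4 over the list alone, adjusted p = 1.65e-07, but adjusted p = 0.125 with an estimated correlation). Genes that fell in FRTL5 had positive differences, such as Tcp11l2 (1.88 ± 0.39), Ech1 (1.38 ± 0.27), Btg1 (1.13 ± 0.19) and Dbp (0.97 ± 0.17). The clock list (median 0.31, adjusted p = 0.0021; 1 called, 3 over the list alone) and the lysosomal list (median 0.36, adjusted p = 0.0035; 0 called in limma, 4 over the list alone) were positive, but had adjusted p = 0.0757 and 0.058 with an estimated correlation. The immediate early list had an adjusted p of 0.0735 and passed in the blocked fit (adjusted p = 0.0491). It also passed without FRTL5 17 h replicates 2 or 3, FRT/TSHR basal replicate 2 or FRT/TSHR 17 h replicates 1 or 2 (0.0434, 0.0375, 0.0429, 0.0294 and 0.0297). Without FRTL5 17 h replicate 1 the thyroid and antioxidant lists passed (0.0328 and 0.0117), the latter also without FRT/TSHR basal replicate 2 (0.0459). The ribosome biogenesis list passed without FRTL5 17 h replicate 2, FRT/TSHR basal replicate 1 or FRT/TSHR 17 h replicate 3 (0.0484, 0.0273 and 0.0135), and without this last array the ER and glycolysis lists passed too (0.0162 and 0.0219).

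In limma 69 probe sets differed in their 17 h response, 27 positive and 42 negative, and the blocked fit called 148, among them all 69. The count was 33, 34, 35, 37, 39, 40 and 42 without FRT/TSHR 17 h replicate 1, FRTL5 17 h replicate 2, FRT/TSHR 17 h replicate 2, FRT/TSHR basal replicate 3, FRTL5 17 h replicate 3, FRTL5 basal replicate 3 and FRT/TSHR basal replicate 1. Of the 26 named genes called here, 11 lost their call in at least 1 fit without an array, 12 in a fit of only the 12 arrays compared and 8 without the FRTL5 arrays numbered 1. Mvd, Top2a and Tcta lost it in 10 of 12 fits, with adjusted p up to 0.118 (without FRTL5 17 h replicate 2), 0.113 and 0.113 (without FRT/TSHR basal replicate 1). Cdk1, Tcp11l2, Prim1, Dnmt1 and Ech1 lost it in 9, 8, 7, 7 and 5 fits, with adjusted p up to 0.0887, 0.111, 0.0658, 0.0808 and 0.0740 (without FRT/TSHR 17 h replicate 1 for Cdk1 and Ech1, and without FRT/TSHR basal replicate 1 for the others). Because the lines also differed in hormone dose and medium, none of these differences can be assigned to the line alone.

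The effects of TSH in both lines were also compared across probe sets, which are not independent replicates. Over all 8740 probe sets the log2 differences correlated at r = 0.138 (Spearman's rho 0.0192) at 30 min and r = -0.0952 (rho -0.0062) at 17 h, with jackknife standard errors of 0.224 and 0.143. Of the 21 probe sets that rose in FRTL5 at 30 min, 19 had a higher value in FRT/TSHR, with medians of 2.08 in FRTL5 and 0.31 in FRT/TSHR. At 17 h 116 of 311 (37.3%) had the same sign, and the medians were 0.92 and -0.09 for the probe sets that rose and -0.72 and 0.01 for those that fell. No call was shared between lines at either time, and the overlap of independent lists is 0 because limma called 0 in FRT/TSHR.

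**Figure D3:**
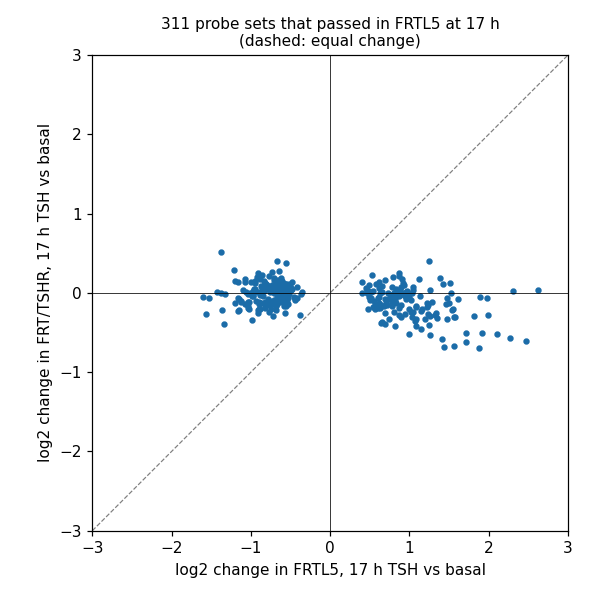
Change at 17 h of TSH against basal (log2) in FRT/TSHR (vertical) against FRTL5 (horizontal) for the 311 probe sets that passed in FRTL5; each point is a probe set and the dashed line marks equal change. The medians on the vertical axis were -0.09 for those that rose and 0.01 for those that fell. Single points lay further from 0, such as Plk4 at -0.68 and Tcp11l2 at 0.51. The changes in the 2 lines correlated at r = -0.408 over these probe sets, and 37.3% had the same sign.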

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

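Of the tests weighed here, only the regrouping of arrays was chosen before its result was seen, and the others were chosen after it. The rule set beforehand for the regrouping used all splits, not only those that part all pairs of arrays. The results in this part stood out because the TSH effect differed between lines, as tested with an interaction term in limma (FRT/TSHR effect minus FRTL5 effect, n = 3 per group). At 30 min these were 3 probe sets, Nr4a1 (-3.29) and Nr4a3 (-1.38), and the medians of the immediate early (-0.41) and mitosis (-0.28) lists. At 17 h they were 69 probe sets. Negative differences were those of Acat2 (-2.83), Slc5a5 (-2.58), Cyp51 (-2.28), Fdps (-2.27), Tubb5 (-1.81), Cdk1 (-1.79), Kcnj15 (-1.69), Mvd (-1.66), Dnmt1 (-1.65), Ddah1 (-1.61), Top2a (-1.50), Hsd17b7 (-1.50), Prim1 (-1.42), Gpx2 (-1.35) and Tyms (-1.21). Positive ones were those of Tcp11l2 (1.88), Ech1 (1.38), Cpq (1.22), Golgb1 (1.16), Btg1 (1.13), Itm2b (1.12), Tcta (0.99), Dbp (0.97), Neurl2 (0.95), Mxi1 (0.92) and Spint2 (0.69). The list medians were -1.08 for cholesterol synthesis, -1.06 for DNA replication, -0.63 for mitosis, 0.31 for clock genes and 0.36 for lysosomal genes.

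Limma called 0 probe sets in FRT/TSHR at 30 min and at 17 h, while it called 21 and 311 in FRTL5. At an unadjusted p under 0.05 there were 208 and 108 in FRT/TSHR, fewer than unchanged probe sets would give. The spread between FRT/TSHR arrays was not larger, as the ratio of the median SD, FRT/TSHR over FRTL5, was 0.919. This ratio decides little, because limma used the same spread estimate per probe set for both lines (median SE 0.146 in each TSH comparison). The values spoke against a response of the same size that limma missed, since the probe sets that rose in FRTL5 had FRT/TSHR medians of 0.31 at 30 min and -0.094 at 17 h. A candidate explanation is that the genes already stood at their stimulated level, and for 53.2% (76 of 143) of the probe sets that rose at 17 h the basal FRT/TSHR mean was at or above the FRTL5 17 h mean, against 39.5% of all probe sets. This left the explanation open for the 17 h genes, and it does not cover Slc5a5, which was lower in FRT/TSHR. The genes that rose at 30 min were not part of this test. Of those named in advance, Egr1, Nr4a1 and Fos had basal FRT/TSHR means of 6.04, 5.17 and 6.98. These lay below their FRTL5 30 min means of 10.78, 9.35 and 10.00, so the explanation does not cover them. Myc, by contrast, was already higher in basal FRT/TSHR than in FRTL5 at 30 min.

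The DNA replication and mitosis lists were lower in FRT/TSHR at both times with the preset correlation, but with an estimated correlation they did not pass (adjusted p = 0.436 and 0.076 at 30 min, 0.355 and 0.0757 at 17 h). In the 12 camera tests without 1 basal array the highest adjusted p was 0.000829. These tests used the preset correlation, so they do not decide whether a single high basal array gave the fall. At 30 min the mitosis medians fell in each pair of arrays with the same number (7.498 to 6.616, 6.956 to 6.767 and 7.038 to 6.867). The DNA replication medians went from 7.21 to 6.449, but in the other pairs only from 6.955 to 6.942 and 6.95 to 6.933. In camera that list no longer passed without 30 min replicate 1 (adjusted p = 0.238) or 17 h replicate 1 (adjusted p = 0.634). At 30 min as large a median over both lists came from 2 of 10 splits (real -0.30, highest other 0.32). By the rule set beforehand, variation between cultures that does not follow TSH may therefore have given this fall. Of the 4 splits that part all pairs only the real one gave as large a median (highest other 0.27). These are too few for a share under 0.05, and the cause at 30 min was left open. At 17 h variation between cultures that does not follow TSH may have given the fall, since 3 of 10 splits and 2 of the 4 that part all pairs gave a median as large, the real one included (real -0.36, highest other 0.39). The median change between 17 h and 30 min was -0.00761, which does not separate displaced basal arrays from a fall that lasted.

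The FRTL5 arrays numbered 1 stood apart from the others. More 3' signal, as from shorter RNA, may be a cause, since their lowest beta-actin 3' minus 5' difference lay 0.85 (log2) above the highest of the other 15 arrays. A batch shared by all arrays numbered 1 may be another, since these 6 arrays took 6 of the 6 lowest places for the BioB spike-in. Whether they made the FRTL5 17 h calls was left open. Without them limma called 239 probe sets, of which 172 were among the 311, and the direction kept by 100% of the 311 is no test, as 4 of the 6 arrays were the same.

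The arrays were also regrouped to see how many probe sets limma then called. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split and the highest other gave 21 and 4 for FRTL5 at 30 min, 311 and 0 at 17 h, 368 and 1 between these times, and 2226 and 0 for the basal lines, with 1 of 10 splits as large each time. In FRT/TSHR they gave 0 and 0 at 30 min and at 17 h, and 0 and 1 between the times, so 10 of 10 splits were as large. For the difference of the 30 min effects 11 of 100 splits gave as many as the real 3 (highest 16), so chance was not excluded, and 9 of the 10 others kept the FRTL5 labels. For the difference of the 17 h effects 2 of 100 gave as many as the real 69, under the share of 0.05 set beforehand. Of the 15 splits that part all pairs of arrays 2 did, the real one included (highest other 87). These 15 are too few for a share under 0.05, so among them chance was not excluded. The split with 87 kept the FRTL5 labels, so the FRTL5 response stayed in it. The 89 splits that did not keep these labels gave at most 1.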

How the results depend on the processing

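Re-centring, quantile normalization and the low-signal filter moved no count of probe sets by over 1.5 times, and no called named gene reversed in any alternative. Calls of named genes were lost in at least 1 alternative for 7 of 8 in FRTL5 at 30 min, 31 of 48 at 17 h and 2 of 10 between the times, 9 of 100 between the basal lines, and 1 of 2 and 16 of 26 for the differences at 30 min and 17 h. The 9 between the basal lines include losses in the fits with a block in each line, whose limit is given below. Other settings did move counts, and the cause was not tested. For FRTL5 at 30 min (21) they were 2 with only the arrays compared, 48 with array weights, 40 with a block within each line, 48 with crossed numbers, 45 without the FRTL5 arrays numbered 1 and 52 without all arrays numbered 1. In that order, for FRTL5 at 17 h (311) the first 4 were 96, 600, 867 and 949. The count there was 508 with the replicate block, 91 at 2-fold or more and 109 at an adjusted p under 0.01. For 17 h against 30 min in FRTL5 (368) these 7 values were 189, 878, 916, 962, 584, 116 and 121. For the difference of the 30 min effects (3) the first 6 were 1, 12, 8, 8, 25 and 25, and the count was 1 at an adjusted p under 0.01. For the difference of the 17 h effects (69) they were 22 with only the arrays compared, 210 with weights, 365 within line, 389 crossed, 148 with the block and 13 at an adjusted p under 0.01. Without all arrays numbered 1, limma called 2 in FRT/TSHR at 30 min and 2 between its times. Between the basal lines 999 of 2226 differed at least 2-fold. The crossed numbers exchange FRTL5 30 min replicates 2 and 3. Their deviations resembled the other number more in the 17 h group (r = 0.628 and 0.611, against 0.233 and 0.148 for the same number). In the basal group they resembled the same number more (r = 0.474 and 0.399, against 0.391 and 0.269 for the other).

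With 1 array left out the counts ranged from 12 to 44 for FRTL5 at 30 min, 152 to 253 at 17 h and 145 to 270 between these times. They ranged from 1 to 24 and from 33 to 83 for the differences at 30 min and 17 h, from 0 to 8 between the times in FRT/TSHR, and from 1877 to 2068 for the basal lines. In FRT/TSHR they stayed at 0 at 30 min and at 17 h, where limma gave 208 and 108 at an unadjusted p under 0.05 with all arrays. The ER list in FRT/TSHR at 17 h reversed without 17 h replicate 3 (adjusted p = 0.982), and its adjusted p was 2.30e-07 without 17 h replicate 2. The correlation of effects between lines was 0.616 at 30 min and -0.408 at 17 h over the probe sets called in at least 1 line. The replicate block ended no call of a gene taken by the naming rule. Beyond the values in the report it brought these under an adjusted p of 0.05: between the basal lines Nkx2-1 (0.0077) and Aif1 (0.0223), in FRTL5 at 17 h RT1-M3-1 (0.00438), Tjp1 (0.00777), Rapgef3 (0.00919), Rhob (0.0173), Hspa4 (0.0193), Nr1d2 (0.0209), Fgf1 (0.0210), Hspd1 (0.0353), Pkm (0.0424), Kif11 (0.0453) and Dkc1 (0.0458), and for the difference of the 17 h effects Per2 (0.0384), Prim2 (0.0384), Lamp1 (0.0403), Gclm (0.0453) and Mcm5 (0.0489). It changed no other such call. The block within each line and the crossed block each ended 6 named calls, all between the basal lines. For that comparison both fits set the lines against each other at the level of the arrays numbered 1, not at the group means. These 6 losses therefore do not show what the pairing changes.

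Without the FRTL5 arrays numbered 1 these FRTL5 17 h calls were lost: Irf7 (adjusted p = 0.0588), Gsta4 (0.0580), Top2a (0.0696), B2m (0.0754), RT1-CE16 (0.0766), Kank2 (0.0807), Pdia6 (0.0822), Slc16a1 (0.0870), Per2 (0.0876), Lamp1 (0.0983), Id1 (0.106), Pnrc1 (0.119), Ctsb (0.121), Pgam1 (0.185), Mcm5 (0.195), Hspe1 (0.236), Ret (0.281) and Ctsh (0.306), while Pax8 passed (0.0360). For the difference of the 17 h effects Cdk1 (0.05, just over the threshold), Spint2 (0.0504), Tcp11l2 (0.0519), Dbp (0.0541), Ech1 (0.0591), Prim1 (0.0684), Top2a (0.0883) and Tcta (0.121) were lost. Mcm6 between the FRTL5 times (0.179) and Nr1d2 between the basal lines (0.0506) were lost, and Fos (0.0220) and Nkx2-1 (1.02e-07) between the basal lines and Fos for the difference at 30 min (3.58e-05) passed. The mitosis list for the difference at 30 min was lost (0.0710). Lists that then passed were antioxidant enzymes in FRTL5 at 17 h (0.0419) and for the 17 h difference (0.0174), immediate early (0.0230) and MAP kinase feedback (0.0159) in FRT/TSHR at 30 min, thyroid differentiation between the basal lines (0.0188), and cAMP-CREB (0.0208) and G1 cyclins (0.0372) for the 30 min difference. The cause was not tested. With an estimated correlation 6 of 33 list calls passed, and with the block added 1, the immediate early list in FRTL5 at 30 min (adjusted p = 0.00803). The epithelial list between the basal lines then had an adjusted p of 0.0670. With the fry test 14 list calls were lost, among them all those in FRT/TSHR at 30 min and at 17 h. It gained 8, all between the basal lines. The mean of all probe sets of a gene lost 1 list call and gained 7, and re-centring lost 1 and gained 1. Signal over background was not measured, so its limit on faint genes is unknown.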

Other observations

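The test in this part was chosen only after the results were seen, as were its genes and gene families. Some genes outside the lists that passed at 17 h in FRTL5 are given here, picked by hand and without a test of a shared function. The amino acid transporter genes Slc7a1 and Slc7a5 rose by 0.96 ± 0.17 and 0.94 ± 0.21, the serine synthesis gene Phgdh by 0.97 ± 0.17, and the one-carbon genes Mthfd1 and Ahcy by 1.05 ± 0.16 and 1.29 ± 0.17 (log2, SE, adjusted p under 0.05 each in limma). The lipid gene Acly rose by 1.08 ± 0.26, the pentose phosphate gene Tkt by 1.08 ± 0.14, and Dnmt1, which maintains DNA methylation, by 1.25 ± 0.23. Klf9, Papss2 and Icam1 fell, with differences of -1.07 ± 0.24, -1.08 ± 0.23 and -0.86 ± 0.21. None of these genes passed in FRT/TSHR.

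Gene families picked by symbol were tested with camera in 18 tests. In FRTL5 at 17 h all 24 proteasome subunit genes had higher values (3 called, median 0.30, adjusted p = 2.04e-07), as did 26 of 27 NADH dehydrogenase genes (2 called, median 0.53, adjusted p = 9.66e-10). Both had adjusted p = 0.0883 with an estimated correlation. The RT1 family had 3 of 17 genes called down (adjusted p = 0.0038, but adjusted p = 0.102 with an estimated correlation). The cathepsin family was lower (4 of 9 higher, adjusted p = 0.0457, but adjusted p = 0.0929 with an estimated correlation), and the ribosomal protein and S100 families did not pass (adjusted p = 0.686 and 0.536). In FRT/TSHR the proteasome (5 of 24 higher) and S100 families (0 of 8 higher) were lower and the cathepsins (7 of 9 higher) higher, with adjusted p = 0.0038, 0.026 and 0.0457, but adjusted p = 0.239, 0.0883 and 0.0929 with an estimated correlation. The NADH dehydrogenase, ribosomal protein and RT1 families did not pass there (adjusted p = 0.821, 0.821 and 0.686). The 17 h effect differed between lines for the proteasome, NADH dehydrogenase, cathepsin and RT1 families (adjusted p = 9.05e-09, 6.92e-08, 0.0129 and 0.0148, but adjusted p = 0.0883, 0.0929, 0.0883 and 0.175 with an estimated correlation), and not for the ribosomal protein and S100 families (adjusted p = 0.686 and 0.821).

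A hypothesis is that TSH moved FRTL5 expression toward that of FRT/TSHR cells, in which the DNA replication and cholesterol synthesis lists were higher, although not with an estimated correlation (adjusted p = 0.673 and 0.132). The test compared basal FRT/TSHR with 30 min FRTL5 arrays, so that no array was shared with the basal FRTL5 group. Of the 311 probe sets that passed at 17 h, 85.5% (266) had the same sign there, 117 of 143 that rose and 149 of 168 that fell. The share was 84.6% to 86.2% with 1 array left out. This range is no test, as the 311 were not chosen again and most arrays stayed the same. Over all probe sets the share was 54.4% and the changes correlated at r = 0.379. The correlation with basal FRT/TSHR arrays was 0.909 for basal and 0.924 for 17 h FRTL5 arrays. This is consistent with the hypothesis, while Slc5a5 moved away from FRT/TSHR, and proliferation or the medium might account for the shared direction.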
